A study of Mus musculus with 6 samples.

How the data were processed

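Poly(A) RNA of the mouse mammary carcinoma line 4T1 was sequenced in 6 libraries, 3 from cells labelled 0 nM and 3 from cells labelled 100 nM perfluorooctane sulfonate (PFOS), a persistent fluorinated surfactant, after 35 passages. Per the labels' protocols, the libraries kept strand by dUTP marking and were read in pairs. The deposited values are FPKM (fragments scaled by transcript length and by the mapped total) per gene, written to 2 decimals for 28418 genes in each library. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used, and the builds GRCh38 and mm10 are both named. The gene identifiers are mouse, 28350 of the 28418 are in the GENCODE M21 annotation of GRCm38, and 25640 have the same chromosome, start and end there, so coordinates are given as in the deposited tables and belong to GRCm38. Symbols and gene types were taken from that annotation, and 68 identifiers had none. The role of GRCh38, the tool versions and whether strand was used in quantification are not given in the sources used here.

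No read counts were used. The test for FPKM that was set before the data were examined was therefore applied: limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), 100 nM minus 0 nM, two-sided, with genes of a mean of at least 1 FPKM over the 6 libraries. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, so FPKM means with SD are given beside them. The files hold no depth. Low values were searched for the size of 1 read, but 25.4% to 29.0% of those examined lay within 0.1 of a whole multiple, so reads were not recovered. The most common step of low values, searched within preset bounds, gave a relative depth of 0.910 to 1.09 across libraries. As reads were not recovered, that range is uncertain, and the precision of single values is known only from the replicates.

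Gene lists were fixed before the data were examined. They cover PPAR targets and fatty acid oxidation, the AhR, CAR and PXR xenobiotic response, the NRF2 antioxidant response, cholesterol biosynthesis, fatty acid synthesis, mesenchymal markers, epithelial markers, extracellular proteases and their inhibitors, cell cycle, p53 targets and cell cycle arrest, the integrated stress response and serine synthesis, the endoplasmic reticulum unfolded protein response, glycolysis and hypoxia response, nuclear-encoded oxidative phosphorylation, the type I interferon response, MHC class I antigen presentation, cytokines, chemokines and NF-kB targets, TGF-beta and YAP targets, the Wnt and Notch pathway, stem cell and mammary lineage markers, ABC transporters, fibroblast, endothelial and muscle markers, leukocyte markers, mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

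Genes are named by a rule fixed in advance. It takes the 6 highest and the 6 lowest fold changes among changed genes whose groups do not overlap and whose higher mean is at least 2 FPKM, the 2 changed members of each list with the smallest adjusted p, and the 3 smallest p-values overall. Predicted genes, RIKEN clones, pseudogenes and clone-type symbols were excluded from the first and last parts. This gave 49 genes, of which 2 are not reported here. Other genes named were chosen after their values were seen.

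The tests were checked on simulated data. In a simulated 100 nM against 0 nM comparison of 11664 genes, 52% of 50 genes changed by 1.2-fold were recovered, 82% at 1.5-fold, 90% at 2-fold and 96% at 4-fold. Of 167 calls, 7 were false, and simulated unchanged data gave 0 calls. The simulated noise was normal and independent between genes, so error rates under deviations shared by many genes were not checked. For each tested gene, the share of 31-base words also found in transcripts of other genes was computed. Of 11731 genes with a sequence, 2495 shared at least 10%. After the data were seen, protein-coding genes with a mean of at least 2 FPKM were grouped in 5 Mb windows holding at least 8 of them. Each window's statistic was the sum of rank-normalised fold changes divided by the square root of the number of genes. Its absolute value was compared with the largest over all windows in each of 10000 shuffles of gene positions. Windows were called at a permutation p under 0.05. Alternatives covered normalization, filters, pseudocounts, moderation, the replicate number as a block and leaving out each library. Added after seeing the data were 2 further scalings, protein-coding genes only, removal of the GC trend, leaving out the called windows, and leaving out replicate 3 of both groups. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.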

Results

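The series asks how the transcriptome of 4T1 cells, a mouse line derived from a mammary tumour and used as a model of triple-negative breast cancer, differs after long culture with PFOS. Expression was given as FPKM for 28418 genes in 3 libraries at 0 nM and 3 at 100 nM PFOS, each labelled as taken after 35 passages. Library sums lay close together at 307920 ± 1089 FPKM (SD, n = 3) at 0 nM and 307910 ± 1348 FPKM (SD, n = 3) at 100 nM, and 21042 to 21591 genes were above 0. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Log2 profiles correlated across genes at 0.988 to 0.994 within groups and at 0.984 to 0.993 between groups. The first principal component held 34.9% of the variance and set replicate 3 at 100 nM apart from the other 5 libraries (score 19.4, others -9.57 to 0.06).

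Cells at 100 nM PFOS had lower transcript levels of the chemokine genes Cxcl1 and Cxcl5, of the immediate early gene Egr1 and of the urokinase gene Plau, and higher levels of the epithelial genes Cdh1, Jup, Dsp, Krt7 and Krt19. Differences were small. Of 11741 genes tested, 487 changed (limma with Benjamini-Hochberg adjustment), 198 higher and 289 lower at 100 nM, with a median absolute difference of 0.23 on the log2(FPKM + 1) scale. A ratio of mean FPKM of at least 1.5 either way was reached by 41 of them. Changed genes past 2-fold by that ratio were Rn7s2 (3.10), Snord88c (2.52), Zfp469 (2.14), Skida1 (2.05), H3f3c (2.00), Pla1a (0.475) and Nipal4 (0.486). Of these, Rn7s2, Snord88c and Zfp469 had means under 1 FPKM at 0 nM (0.990, 0.653 and 0.957), so their ratios rest on low values. Snord88c is a small nucleolar RNA gene of 90 bases, and H3f3c is annotated as a processed pseudogene. On the log2(FPKM + 1) scale, which understates the change of low genes, 1 gene, Rn7s2, passed 2-fold. Values of the groups did not overlap for 26.9% of the tested genes, where chance gives 10%. The count fell to between 122 and 290 genes when 1 library was left out, and each of the 6 libraries moved it by over 1.5 times. It was 156 when genes in stretches of neighbouring genes that moved together were left out and the test was rerun. Of the 487, 302 lay outside those stretches, so losing the genes inside them accounts for only part of that fall. Without replicate 3 of both groups the count was 91.

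On the log2(FPKM + 1) scale the lowest fold change among named genes was that of Egr1, a serum-responsive transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), at 13.7 ± 0.45 FPKM (SD, n = 3) at 0 nM and 7.11 ± 0.43 FPKM (SD, n = 3) at 100 nM. Its difference was -0.86 ± 0.05 (SE) on the log2(FPKM + 1) scale, with a limma adjusted p of 0.000991. Pla1a, a phosphatidylserine phospholipase, went from 5.21 to 2.48 FPKM, Gipc2 from 10.1 to 5.21, Syde2 from 10.01 to 5.70 and Nipal4 from 2.48 to 1.21. By ratio of mean FPKM, Pla1a (0.475) and Nipal4 (0.486) lay below Egr1 (0.518). Pla1a lies on chromosome 16 and Gipc2 and Syde2 on chromosome 3, in stretches described below where most genes were lower. Egr1 lies in a 5 Mb window of chromosome 18 where 24 of 27 genes were lower, with a median difference of -0.05. That window was not called (permutation p = 0.0608 adjusted over windows). Among the higher genes, Skida1 went from 2.10 to 4.31 FPKM, Zfp469 from 0.957 to 2.05, Ctsw, a cysteine protease gene, from 6.09 to 9.60, Tmem54 from 11.2 to 17.2 and Cyb5d1 from 4.13 to 6.88. Cyb5d1 overlaps Naa38 on the other strand and shares 50.1% of its words with other transcripts, and Ctsw and Tmem54 overlap genes on the other strand. Rn7s2, a signal recognition particle RNA, went from 0.990 to 3.07 FPKM but shares 100% of its words with copies, so its value is uncertain. The smallest p-value was that of Odc1, the ornithine decarboxylase of polyamine synthesis (chromosome 12, 17544794 to 17551084), at 657 ± 6.67 FPKM (SD, n = 3) against 460 ± 1.73 FPKM (SD, n = 3), with a limma adjusted p of 0.000188; 52.0% of its words are shared with other transcripts. Gng5 (33.9 to 21.8 FPKM) and Hs2st1 (40.4 to 28.8 FPKM), next by p-value, lie in the same stretch of chromosome 3. Over the alternatives run for each, the call was lost in 7 of 17 for Rn7s2, 6 of 18 for Syde2, 3 of 19 for Ctsw, 2 of 19 for Cyb5d1, 1 of 18 for Nipal4 and 1 of 17 for Zfp469.

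**Figure D1:**
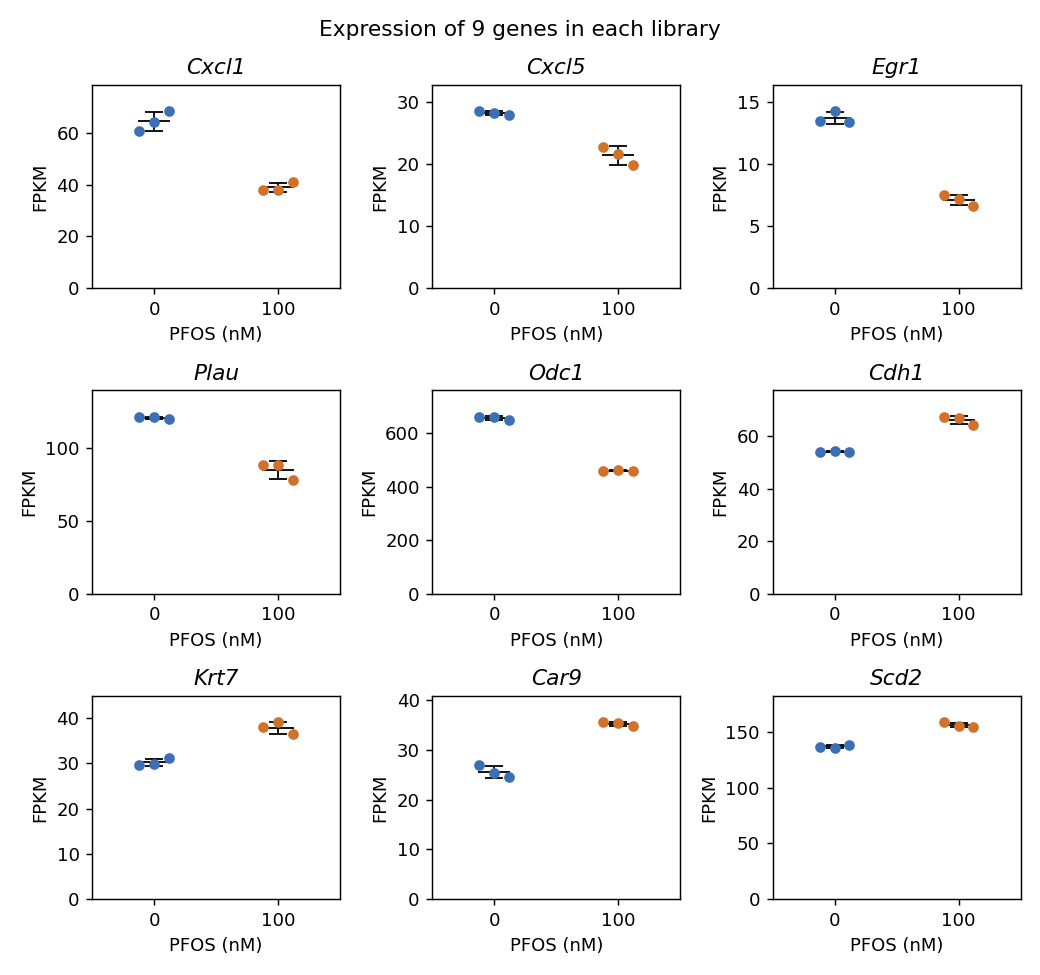
FPKM (vertical axes, from 0) of 9 named genes in the 3 libraries at 0 nM (blue) and the 3 at 100 nM PFOS (orange); each point is a library, and the black bars are the mean and SD of the 3 libraries. Cxcl1 lay between 60.87 and 68.31 FPKM at 0 nM and between 37.91 and 41.06 FPKM at 100 nM, and Cdh1 between 53.82 and 54.36 and between 64.42 and 67.35.

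Among cytokines, chemokines and NF-kB targets, 5 of 28 measured members fell and 0 rose; 13 fell adjusted over the list alone. Cxcl1, a neutrophil-attracting chemokine (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), went from 64.4 ± 3.73 to 39.0 ± 1.80 FPKM (SD, n = 3 each; limma adjusted p = 0.00223), and its neighbour Cxcl5 from 28.2 to 21.4 FPKM. The others were Csf1, the macrophage colony-stimulating factor, at 42.5 and 37.2 FPKM, Nfkbiz at 9.79 and 8.00 FPKM and Tnfaip3, an inhibitor of NF-kB signalling, at 19.8 and 17.2 FPKM. The list was called lower by camera (adjusted p = 5.43e-06), with adjusted p = 0.071 with an estimated correlation. Of extracellular proteases and their inhibitors, 2 of 25 rose and 3 fell (5 and 3 adjusted over the list alone), with no call for the list (camera adjusted p = 0.655). Plau, which activates plasminogen, went from 121 ± 0.885 to 85.3 ± 5.98 FPKM (SD, n = 3 each; limma adjusted p = 0.00554) and its receptor Plaur from 49.7 to 44.0 FPKM. Over 19 alternatives 1 to 6 cytokine list members changed and 1 to 6 of the proteases. For the cytokine list it was 1 without replicate 1 at 0 nM, and 2 without replicate 2 or 3 at 0 nM or replicate 1 or 2 at 100 nM. The call was lost in 9 of 19 for Csf1, 7 for Nfkbiz, 6 for Tnfaip3, 5 for Cxcl5 and 4 for Plaur.

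Epithelial markers were higher for 5 of 25 measured members and lower for 0 (9 and 0 adjusted over the list alone). Cdh1, which encodes E-cadherin (chromosome 8, 106603351 to 106670246), went from 54.1 ± 0.271 to 66.2 ± 1.59 FPKM (SD, n = 3 each; limma adjusted p = 0.00323), Krt7 from 30.2 to 37.8, Krt19 from 37.9 to 45.1, Jup from 9.94 to 12.3 and Dsp from 7.19 to 9.18 FPKM. The list was called higher by camera (adjusted p = 5.43e-06), with adjusted p = 0.597 with an estimated correlation. Over 19 alternatives 1 to 7 members changed. It was 2 without replicate 1 or 2 of either group and 3 without replicate 3 at 0 nM. Jup lost its call in 9 of 19, Krt19 in 7, Dsp in 5 and Krt7 in 1. Of 16 mesenchymal markers, the collagen gene Col5a1 rose from 6.34 to 7.89 FPKM and the vimentin gene Vim fell from 563 to 516 FPKM; adjusted over the list alone, 2 rose and 1 fell, and the list was not called (camera adjusted p = 0.655). Of 14 stem cell and mammary lineage markers, Itgb4 rose from 7.58 to 9.70 FPKM and Itga6 fell from 22.7 to 19.9 FPKM (1 and 3 adjusted over the list alone; camera adjusted p = 0.181). TGF-beta and YAP targets had 4 higher and 1 lower of 28 (4 and 2 adjusted over the list alone; camera adjusted p = 0.204), among them Pmepa1 at 13.3 and 17.1 FPKM and Ltbp2 at 7.85 and 10.1 FPKM. Ltbp2 lies in a stretch of chromosome 12 where most genes were higher. In the Wnt and Notch pathway, 1 of 15 fell, Nrarp, from 22.4 to 18.4 FPKM (1 adjusted over the list alone; camera adjusted p = 0.508). Over 19 alternatives 0 to 3 mesenchymal, 0 to 2 stem cell, 0 to 6 TGF-beta and YAP and 0 to 1 Wnt and Notch members changed. Itga6 and Nrarp lost their call in 9 of 19 each, Vim in 7, Itgb4 in 5, Col5a1 in 2, Pmepa1 in 1 and Ltbp2 in 1 of 18.

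In cholesterol biosynthesis, 23 of 25 members had a higher mean at 100 nM, with a median difference of 0.09; 2 rose and 0 fell (11 and 0 adjusted over the list alone). Among them was Acat2, at 27.2 and 30.9 FPKM, which shares 50.5% of its words with other transcripts. The list was called higher by camera (adjusted p = 9.83e-06), with adjusted p = 0.071 with an estimated correlation. In fatty acid synthesis 2 of 22 rose, the desaturase gene Scd2, from 137 to 156 FPKM, and the fatty acid synthase gene Fasn, from 55.9 to 60.5 FPKM (2 adjusted over the list alone; camera adjusted p = 0.00828, and adjusted p = 0.248 with an estimated correlation). PPAR targets and fatty acid oxidation had 0 of 19 members past the limma threshold (5 at an unadjusted p under 0.05; 1 lower adjusted over the list alone; camera adjusted p = 0.770), and the AhR, CAR and PXR response had 0 of 7 (2 unadjusted; 0 adjusted over the list alone; camera adjusted p = 0.770). The NRF2 list had 1 of 28, Abcc1, lower at 12.8 and 11.3 FPKM (1 adjusted over the list alone; camera adjusted p = 0.160). Among 13 ABC transporters, 1 rose and 1 fell, the latter being Abcc1 (1 and 2 adjusted over the list alone; camera adjusted p = 0.438). Abcc1 lies in a stretch of chromosome 16 where most genes were lower. Over 19 alternatives 0 to 6 cholesterol, 0 to 2 fatty acid synthesis, 0 to 1 PPAR, 0 to 1 NRF2 and 0 to 2 ABC transporter members changed. The call was lost in 12 of 19 for Fasn, 9 for Acat2, 1 for Scd2 and 8 of 18 for Abcc1. For PPAR targets and for nuclear-encoded oxidative phosphorylation the median was above 0 and the camera direction down, and for the AhR, CAR and PXR list the reverse.

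In glycolysis and hypoxia response, 4 of 31 rose and 2 fell (7 and 2 adjusted over the list alone). The carbonic anhydrase gene Car9 went from 25.5 ± 1.21 to 35.2 ± 0.400 FPKM (SD, n = 3 each; limma adjusted p = 0.0032) and Pgk1, which shares 68.3% of its words with other transcripts, from 791 to 867 FPKM. The camera call (adjusted p = 0.0223) was lost in 7 of 21 alternatives, among them without replicate 3 at 100 nM (adjusted p = 0.121), with adjusted p = 0.254 with an estimated correlation. In nuclear-encoded oxidative phosphorylation 1 of 35 rose, Ndufb10 (30.4 to 33.2 FPKM), and 1 fell, Atp5a1 (268 to 247 FPKM), which lies in a stretch of chromosome 18 with mostly lower genes (1 and 2 adjusted over the list alone; camera adjusted p = 0.869). Of 13 mitochondrially encoded genes, mt-Nd1 fell from 3166 to 2843 FPKM and mt-Co1, sharing 63.9% of its words, from 7114 to 6617 FPKM (4 lower adjusted over the list alone). Their camera call (adjusted p = 0.00685) was lost in 5 of 21 alternatives, among them quantile normalization (adjusted p = 0.207), with adjusted p = 0.622 with an estimated correlation. Over 19 alternatives 1 to 7 glycolysis, 0 to 2 nuclear-encoded oxidative phosphorylation and 0 to 3 mitochondrially encoded members changed. The call was lost in 11 for mt-Co1, 10 for mt-Nd1, 11 for Ndufb10, 5 for Pgk1 and 9 of 18 for Atp5a1. Over the alternatives the difference came to as little as -0.06 for mt-Nd1, and to 0 for mt-Co1 under quantile normalization. That method gives a gene that keeps its rank the same value in every library. A difference of 0 is then fixed by rank and does not bear on mt-Co1. Of 81 cytosolic ribosomal protein genes, 6 rose (8 rose and 1 fell adjusted over the list alone), with Rpl14 at 294 and 339 FPKM and Rpl4 at 1171 and 1332 FPKM. Rpl14 and Rpl4 share 42.7% and 32.2% of their words with other transcripts, and Rpl4 lies in a stretch of chromosome 9 with mostly higher genes. The camera call for ribosomal proteins (adjusted p = 4.98e-05) was lost without replicate 3 at 100 nM (adjusted p = 0.0656), with adjusted p = 0.622 with an estimated correlation. Over 19 alternatives 0 to 8 ribosomal protein genes changed, and the call was lost in 1 for Rpl14 and in 3 of 18 for Rpl4. None of 27 replication-dependent histone genes passed in the limma test (5 unadjusted; 0 adjusted over the list alone; 0 to 2 over the alternatives; camera adjusted p = 0.301).

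For growth and stress genes, 2 of 32 cell cycle members fell and 0 rose (2 lower and 1 higher adjusted over the list alone). They were Ccne1, which encodes cyclin E1, at 6.92 and 5.01 FPKM, and Mcm4, a replicative helicase subunit in the chromosome 16 stretch, at 62.4 and 54.7 FPKM. The camera call (adjusted p = 0.0106) was lost without replicate 3 at 100 nM (adjusted p = 0.0650), with adjusted p = 0.597 with an estimated correlation. In the integrated stress response and serine synthesis, 3 of 24 fell and 1 rose (4 and 1 adjusted over the list alone), with Chac1 at 7.32 and 5.36 FPKM and Asns, the asparagine synthetase gene, at 91.1 and 79.5 FPKM. That list's camera call (adjusted p = 0.00685) was lost without replicate 1 at 100 nM (adjusted p = 0.0714), with adjusted p = 0.597 with an estimated correlation. The p53 list had 3 higher and 1 lower of 18 (3 and 1 adjusted over the list alone; camera adjusted p = 0.334), with Gadd45b at 17.0 and 22.7 FPKM, in a mostly higher stretch of chromosome 10, and Plk2 at 46.1 and 38.3 FPKM. In the unfolded protein response, Pdia4 rose from 44.97 to 49.7 FPKM and Pdia6 fell from 118 to 106 FPKM among 22 (1 and 3 adjusted over the list alone; camera adjusted p = 0.508). Over 19 alternatives 0 to 3 cell cycle, 0 to 5 integrated stress response, 0 to 4 p53 and 0 to 4 unfolded protein response members changed. The call was lost in 10 of 19 for Pdia4, 7 for Ccne1, 6 for Pdia6, 5 for Asns, 2 for Chac1 and 1 for Plk2, and in 7 of 18 for Gadd45b and 2 of 18 for Mcm4.

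Of 27 type I interferon response members and 20 of MHC class I antigen presentation, 0 and 0 passed the limma test (1 and 2 at an unadjusted p under 0.05, and 0 and 0 adjusted over the list alone), although camera called both lists higher (adjusted p = 0.00391 and 0.0361), with adjusted p = 0.655 with an estimated correlation for each. Isg15, a ubiquitin-like interferon-induced gene, stood at 46.4 FPKM in replicate 3 at 100 nM and at 15.54 and 9.72 FPKM in replicates 1 and 2, against 7.67 to 9.10 FPKM at 0 nM. Without replicate 3 at 100 nM the adjusted p was 0.503 for interferon and 0.582 for MHC class I. The MHC class I call was also lost without replicate 1 or 2 at 0 nM (adjusted p = 0.105 and 0.186). Of 21 alternatives 5 ended the interferon call and 7 the MHC class I call. The same library held T cell transcripts such as Gzmb, at 14.94 FPKM and at most 0.05 FPKM in the other 5. Of 12 leukocyte markers 0 passed the limma test (0 unadjusted; 0 adjusted over the list alone; 0 to 1 over the alternatives; camera adjusted p = 0.264), with a median difference of 0.26 and Cd14 at 65.16 FPKM in that library against 8.41 to 24.14 FPKM in the others. Camera called the leukocyte list without replicate 1 at 100 nM (adjusted p = 0.000193). Of the fibroblast, endothelial and muscle markers 1 was measured, Pdgfra, which did not pass (adjusted p = 0.671 by limma; 0 adjusted over the list alone).

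**Figure D2:**
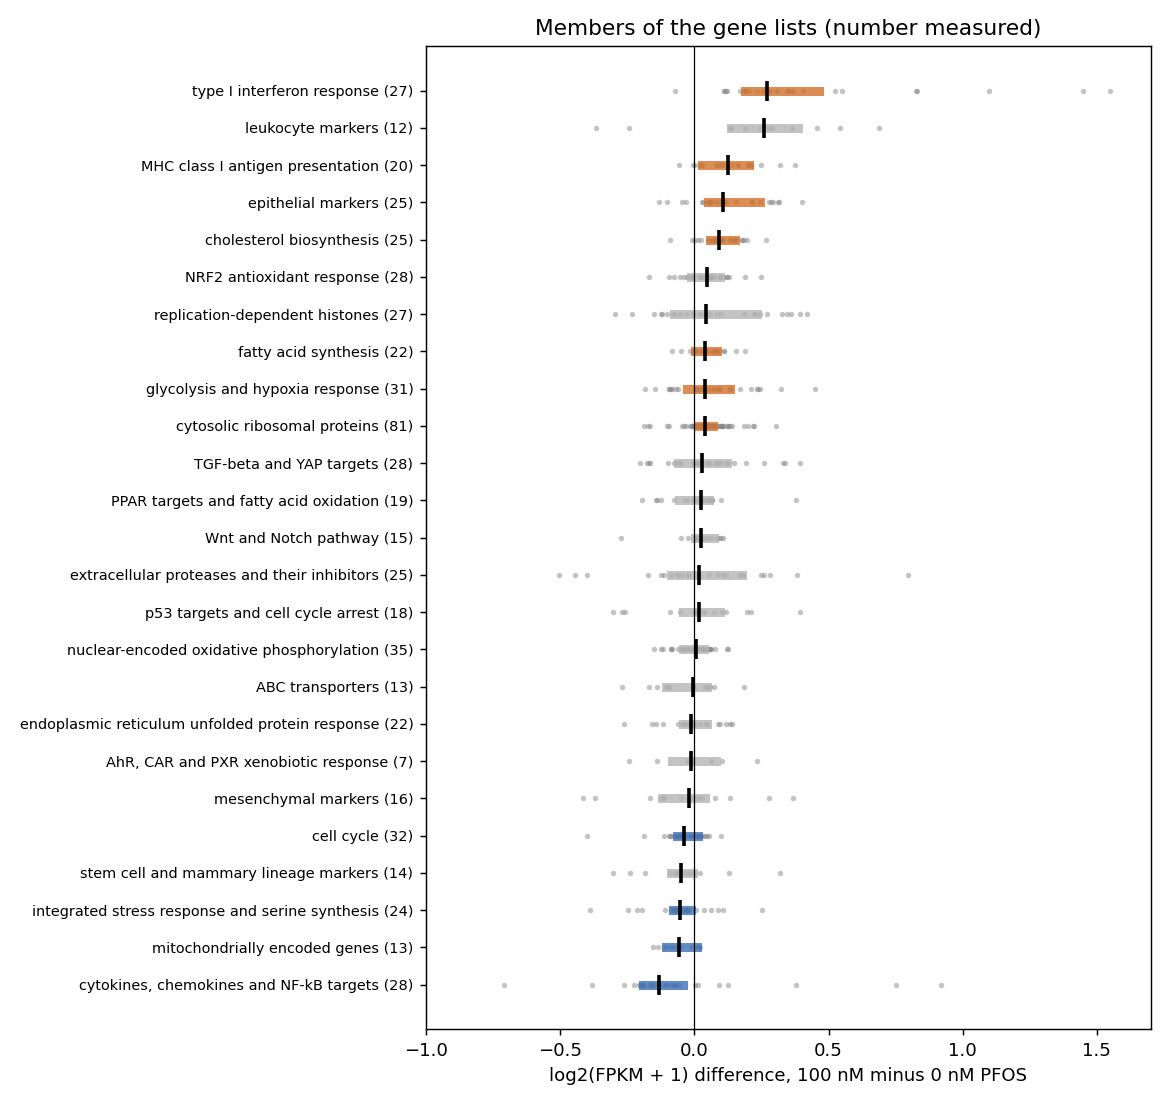
Difference in log2(FPKM + 1), 100 nM minus 0 nM PFOS, for members of the tested gene lists (grey points), with the median (black tick) and the middle 50% of members (bar; orange called higher by camera, blue called lower, grey not called). The cytokine list has a median of -0.13 and the epithelial list one of 0.11.

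Lower expression also ran along chromosomes, in a scan chosen after seeing the data. Of 360 windows of 5 Mb, 16 were lower and 18 higher at 100 nM at a permutation p under 0.05 adjusted over windows, from shuffled gene positions. Such a p-value measures how fold changes cluster along the genome, not the spread between libraries or cultures. On chromosome 3 from 140 to 155 Mb, 31 of 32 scanned genes were lower and 21 passed the limma test, with a median difference of -0.29 and a median FPKM ratio of 0.802. On chromosome 16 from 30 to 45 Mb, 65 of 68 were lower and 40 passed, with a median of -0.24 and a ratio of 0.824. From 10 to 25 Mb of chromosome 16, 88 of 92 were lower, with a median of -0.15. The largest higher stretch by median was on chromosome 9 from 60 to 70 Mb, where 18 of 51 genes passed, with a median of 0.16. Shifts were not confined to called windows. Odc1 and Pdia6 lie in an uncalled window of chromosome 12 where 8 of 8 genes were lower, with a median of -0.07. Asns lies in one of chromosome 6 where 8 of 10 were lower, with a median of -0.11. Rpl14 lies in one of chromosome 9 where 6 of 27 were lower, with a median of 0.06. All tested windows of chromosome 18 had a negative median, from -0.155 to -0.014. On chromosome 9 all tested windows from 60 Mb on had a positive median, from 0.029 to 0.161. The called windows held 11.9% of tested genes and 38.0% of changed genes. They were called from the fold changes of these same libraries, so that contrast follows in part from the selection.

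**Figure D3:**
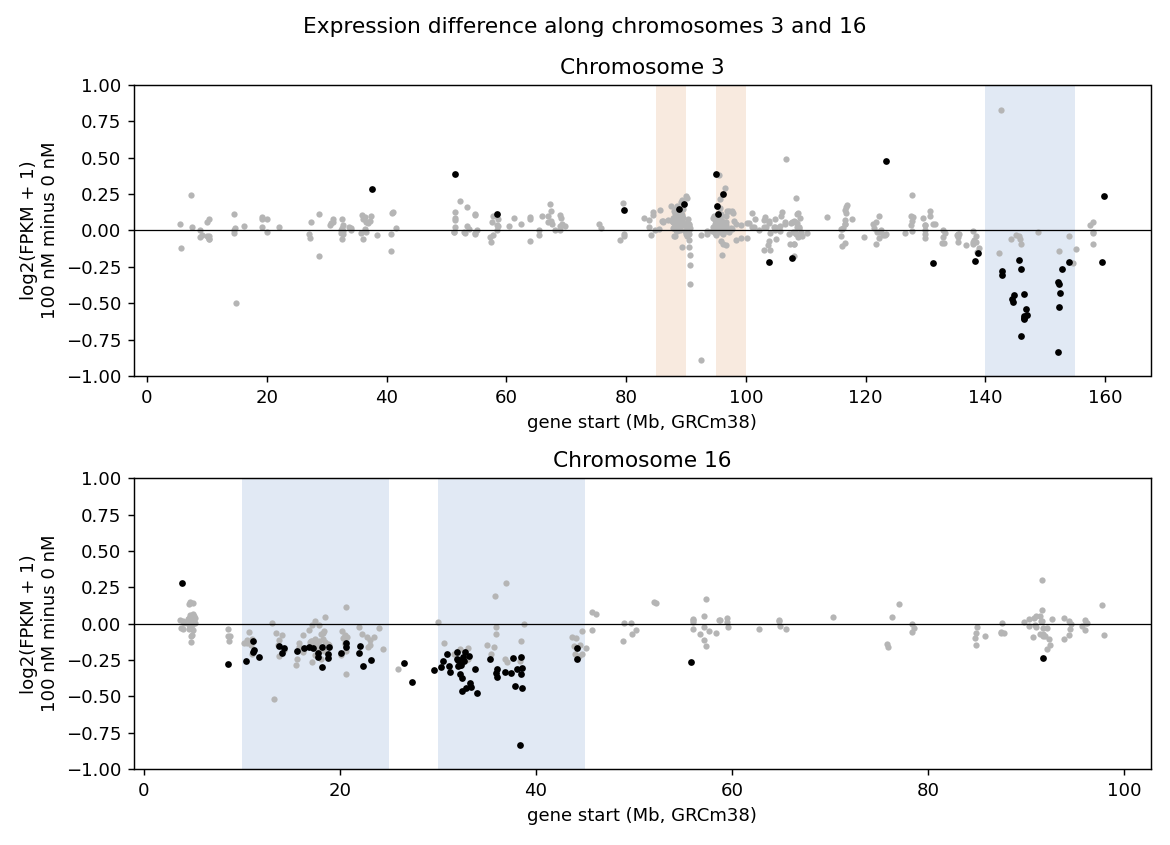
Difference in log2(FPKM + 1), 100 nM minus 0 nM PFOS, against gene start (Mb, GRCm38) for protein-coding genes with a mean of at least 2 FPKM on chromosomes 3 and 16; black points passed the limma test, and shading marks called stretches (blue lower, orange higher). Between 140 and 155 Mb on chromosome 3, 31 of 32 genes lie below 0.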

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

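Leaving out called windows, replicate 3 of both groups, GC trends, non-coding genes and the 2 further scalings were chosen after seeing the data. The count of 487 changed genes (198 higher, 289 lower) was 204 (69 and 135) with no filter on low values, 156 (70 and 86) without the called windows, all 156 being among the 487, and 91 (34 and 57) without replicate 3 of both groups. With 1 library left out it was 122 to 290 (38 to 114 higher, 84 to 176 lower), with fewer samples. Of the 487, 302 lay outside the called windows, so losing the genes inside them accounts for only part of the fall to 156. The cause of the rest of that fall and of the other shifts was not tested. The other alternatives without a block gave 458 to 653 genes. On the log2 scale, the 1 gene past 2-fold was 0 with no filter, with a mean of at least 5 FPKM and with a pseudocount of 5. It was also 0 for protein-coding genes and with the GC trend removed. It was 4 with a pseudocount of 0.1, 4 without replicate 3 of both groups, and 0 to 4 with 1 library left out. The 11 lists called became 0 with an estimated correlation, 5 with fry and 7 to 13 with 1 library left out. The first component held 38.5% over the 500 most variable genes. Over 913 values of the 49 named genes under alternatives, 0 reversed and 709 stayed past the threshold. The groups of all 487 changed genes did not overlap, so leaving out libraries could not reverse a direction. For those alternatives the 0 was fixed by how the genes were chosen and is not a sign of stability. The value of mt-Co1 came to 0 under quantile normalization, which rank alone can fix. In every alternative run for them 12 stayed past it (Car9, Cdh1, Cxcl1, Egr1, Gipc2, Gng5, Hs2st1, Odc1, Pla1a, Plau, Skida1 and Tmem54). Camera lost glycolysis with quantile normalization, a mean of at least 5 FPKM, the GC trend removed, the called windows left out and replicate 3 of both groups left out (adjusted p = 0.0831, 0.0570, 0.110, 0.0767 and 0.0901). It lost mitochondrial genes with quantile normalization, no filter and the GC trend removed (0.207, 0.0548 and 0.0631), and the cell cycle with quantile normalization (0.0579). It lost interferon and MHC class I at a mean of at least 5 FPKM (0.108 and 0.0585) and without replicate 3 of both groups (0.229 and 0.0901), which also ended ribosomal proteins (0.121). Fry did not call epithelial markers (0.0711), the integrated stress response (0.0981), interferon, MHC class I (0.449 each), mitochondrial genes or ribosomal proteins (0.235 each). Camera also lost MHC class I without replicate 1 or 2 at 0 nM (0.105 and 0.186), gained TGF-beta and YAP targets without replicate 3 at 100 nM (0.0188) or of both groups (0.0344), and gained the NRF2 list and the stem cell list without replicate 1 at 100 nM (0.0163 and 0.0385).

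Deviations of same-numbered libraries correlated across genes at -0.033, -0.053 and 0.0065, so they shared no strong deviation. Whether equal numbers mark paired cultures is not given in the labels. With the replicate number as a block, 58 genes changed (11 higher, 47 lower), 57 of them among the 487. Of the 58, 0 passed 2-fold on the log2 scale. Size factors by relative log expression or upper quartile, DESeq2 and limma-voom, planned for counts, were not run because the values are FPKM. Depth is unknown, so no floor was given for low genes.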

Other observations

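Chosen after the results were seen were the tests of gene positions, of single libraries, of DNA copy number, of PFOS exposure and of a mislabelled library, the division of tissue markers by tissue, and the split test of the number of changed genes. The 6 samples make 10 splits, too few for a share under 0.05. The real split gave 487 changed genes and the highest other split 1, with 1 of the 10 as large. For genes past 2-fold on the log2 scale these were 1 and 1, with 2 of the 10 splits as large. For called lists they were 11 and 9, with 1 of the 10 as large.

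Some libraries held transcripts of other tissues. Liver genes were present in replicates 1 and 2 at 0 nM, with Alb at 7.17 and 6.88 FPKM and at most 0.06 FPKM elsewhere. T cell genes were present in replicate 3 at 100 nM, with Gzmb at 14.94 and Trbc2 at 5.99 FPKM, and heart genes in replicate 2 at 0 nM, with Myh6 at 2.08 FPKM. Kidney tubule genes were present in 5 libraries, with Havcr1 at 13.75 to 16.12 FPKM, and Havcr1 was listed at 0 in replicate 3 at 100 nM.

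A candidate source of the liver and T cell transcripts is RNA or reads from other samples. Of 48 liver, T cell and kidney tubule markers written down before their values were seen, 38 reached 0.1 FPKM in some library, and 34 of these (89.5%) were at least 5 times higher in every carrying library than in any other, a carrying library having at least 20% of the highest sum of the markers seen first. That share met the criterion set in advance, but it is left undecided here because of its kidney part. Taken apart after that outcome, 28 of 30 liver and T cell markers (93.3%) fit and 6 of 8 kidney tubule markers (75%) did. Heart markers were not part of the criterion, and 5 of 9 new ones at 0.1 FPKM or more met the same bound. The kidney part decides nothing, because 5 of 6 libraries carry these genes and expression by the line itself, lost in replicate 3 at 100 nM, would give the same. Where RNA entered was not tested. PFOS exposure as the source is argued against by sums that differ within a dose. Liver sums were 29.6, 27.4 and 0.08 FPKM within 0 nM, and T cell sums 2.25, 2.73 and 44.8 FPKM within 100 nM. The criterion asked whether the carrying libraries divided libraries of the same dose. They did for 4 of 4 tissues, but the uneven presence that prompted the test had already fixed that count. That criterion replaced an earlier one after its outcome: summed markers separated the groups for 2 of 4 tissues, but only just, with the lowest T cell sum at 100 nM 2.25 against 2.23 FPKM and the highest kidney sum at 100 nM 46.41 against 46.42 FPKM. Replicate 3 at 100 nM as a mislabelled 0 nM library is argued against by its median difference of -0.27 over the stretches of chromosomes 3 and 16. There the 0 nM libraries had -0.007 to 0.013, and replicates 1 and 2 at 100 nM had -0.25 each. The stretches were selected for low differences that include this library under its label, so the test is not independent of that label.

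The lower stretches on chromosome 3 (140 to 155 Mb) and chromosome 16 (30 to 45 Mb) were weighed together, over 100 genes with a median of -0.25. The scan that selected them also set chance positions aside: their leading windows, at statistics of 7.06 and 11.6, passed the 5.36 that was the highest of 10000 shuffles (permutation p = 0.0001 adjusted over windows, the smallest these can give). A GC trend (median -0.249 after its removal), shared reads (median -0.253 over 68 genes sharing under 1% of words) and a single library (all 3 at 100 nM below the 0 nM range) are argued against. A difference in DNA copy number between the cultures may contribute and was judged by whether 85% of genes were lower with a spread at most 1.5 times that of other genes, and argued against over 2 times. Pooled, 96.0% were lower and the spread was 1.72 times (1.73 about each stretch's own median), which decides neither way. Taken apart after that outcome, chromosome 16 met the criterion at 1.32 times. The scan had selected both stretches for lower genes, so the share of lower genes was largely fixed and only the spread was open. A small spread alone cannot tell a copy number change from another shift shared by neighbouring genes. Chromosome 3, at 3.74 times, went against a change uniform over the whole 140 to 155 Mb. That stretch was bounded by fixed 5 Mb windows and may include genes beyond a shorter change. Its spread therefore cannot argue against a copy number change over part of the stretch. No DNA was measured, and with possibly 1 culture per dose, PFOS and drift between cultures over 35 passages cannot be told apart.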
